A study of Mus musculus with 4 samples.

How the data were processed

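Both deposited pools held cells of the distal small-intestinal epithelium of 8 mice, sequenced with hashtag antibodies. Per the file headers, the matrices are integer counts from Cell Ranger 6.1.2: UMI counts per gene and counts of hashtag antibodies per barcode, without normalization. The deposited feature and barcode lists hold other values, namely gene identifiers, symbols, feature types and cell barcodes. Per the labels, the authors aligned reads to mm10. The authors' hashtag caller and cell filters are not stated. Positions are from GENCODE M21 (GRCm38), in which all 114 named genes were found under the same identifier and name.

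Pool 1 held 3342 barcodes (median 4352.5 UMIs, 1599 genes and 9.8% mitochondrial UMIs) and pool 2 held 2110 (7649.5 UMIs, 2385.5 genes and 18.1%), each with 32285 genes and 8 hashtags. Choices were made before the data were examined unless stated. Hashtags were assigned with HTODemux (Seurat 5.3.0, positive quantile 0.99) in each pool. Pool 1 gave 2257 barcodes with 1 hashtag, 333 with several and 752 with none; pool 2 gave 1772, 160 and 178. The hashtag gave the mouse, and hashtag and pool gave the gate, per the labels. Sex-linked genes matched between gates for 8 of 8 mice. Of the 4029 assigned barcodes, 1993 (49.5%) had at least 1000 UMIs, at least 500 genes and under 20% mitochondrial UMIs.

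Cells were scaled to 10000 counts, log-transformed and clustered in scanpy 1.11.5 (python 3.11.15) with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0. Clusters were named from marker lists fixed beforehand: at least 3 markers among the 50 leading genes and at least 25% of markers raised. A cluster with none was left unnamed. Secretory cells were Paneth, goblet, enteroendocrine, tuft and secretory progenitor cells.

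The mouse was the replicate. Shares per mouse and gate were compared by exact two-sided permutation tests of the difference of means, with Benjamini-Hochberg adjustment over 10 classes, and by exact sign flips within mice. With 4 against 4 the smallest p is 0.0286, with 4 sign flips 0.125 and with 3 against 3 0.1. After adjustment over 10 classes, a class alone at 0.0286 cannot pass, and at 0.125 or 0.1 no class can. Wilson 95% intervals and limits from a count of 0 (3 counts of the total) cover counting error only.

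Counts were summed per mouse and gate (16 sums), over all cells and within each class with at least 10 cells in at least 3 sums per group. They were tested, two-sided, with edgeR 4.0.16 (R 4.3.3; filterByExpr, TMM, quasi-likelihood F-test, pool as covariate). Genes with adjusted p under 0.05 were called. The 5 contrasts were clones against control at 48 h and at 72 h, 72 h against 48 h in clones and in control cells, and the change of the clone-control difference. Clone and control cells of 1 mouse are a pair, so mouse was also fitted as a block. Across genes, which are not independent replicates, the correlation of the residuals of a mouse's clone and control sums was -0.001 to 0.090 in the 48 h mice and 0.222 to 0.555 in the 72 h mice. DESeq2 1.42.0 gave a further test.

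Of 25 gene lists fixed beforehand, 21 had at least 3 tested members: stem, secretory progenitor, Paneth, goblet, enteroendocrine, tuft, immature and mature enterocyte, M cell, G1/S, G2/M, Notch, Wnt, BMP and p53 targets, protein folding, MHC class II, interferon response, stress and immediate early, fetal-like regeneration and oxidative phosphorylation. Of the immune and endothelial lists 1 gene each was tested (Ptprc and Esam), and of the stromal and erythroid lists 0. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, adjusted over lists), with an estimated correlation beside it, and with fry. Medians are given also with genes that had no UMI in a whole group set at the fold that 3 counts over that group allow.

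Named genes were the 10 called genes with the largest change each way among those with average log2 CPM of at least 4 and no overlap between groups (5 within a class), the 3 most abundant members of each list, and 12 fixed genes. Applying the first part to the blocked fit was chosen after the data were seen, as was naming Esr1, all genes called between the control sets and all called in the blocked change between times.

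Counts were simulated from the real means, library sizes and spread, with known changes added to 200 genes. There edgeR recovered 51% of changes of 1 on the log2 scale and 87% of changes of 2 at 48 h, and 76% and 100% at 72 h, with 8 and 7 false calls. With the block it recovered 45% and 87%, and 74% and 100%, with 4 and 6 false calls. The shifted list was called and 0 of 21 unchanged lists were. Each gene was drawn independently, without mouse effects or correlation between genes. False calls that these would cause, in lists or with the block, were therefore not tested.

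Alternatives tried were a Gaussian mixture for hashtags (1115 cells), mitochondrial limits of 10% (1313 cells) and 50% (3323), at least 3000 UMIs (1846), Scrublet, Leiden resolutions 0.6 and 1.5, variable genes without those called within a class, other secretory totals, each pool alone, DESeq2 size factors, no gene filter, no pool term, at least 20 cells per sum, and leaving out each mouse. Scrublet called 3 of 2470 and 3 of 1863 barcodes, 2 of them among the 282 and 144 hashtag doublets, so it is taken not to have worked. Added after the data were seen were the 50% limit, a top hashtag of at least 70% of hashtag counts (1641 cells), both together (2805 cells), sums of at least 10 cells over all cells, named cells alone, goblet and progenitor cells alone, all classes over all mice, and combinations with the block.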

Results

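Single-cell RNA sequencing profiled the distal small-intestinal epithelium of 8 mice that carried Lgr5-EGFP-IRES-CreERT2 and the Rosa26-mTmG reporter. Lgr5 marks the stem cells at the crypt base. In these mice, 4-OH-tamoxifen activates the recombinase in Lgr5-expressing cells, and the reporter then gives those cells and their progeny GFP. Of the 8 mice, 4 were traced for 48 h and 4 for 72 h. From each mouse, GFP-high cells (clones) and GFP-negative cells (control epithelium) were sorted, after villi had been scraped off and cells had been stained for the epithelial marker EpCAM and for CD31 and CD45. The EGFP of the Lgr5 allele and the GFP of the reporter fluoresce alike, so the green signal alone does not tell them apart. Where the GFP-high gate was set, and so whether it parted them by brightness, was not known here. The gates may thus also have sorted cells by Lgr5 expression. Higher Lgr5, stem genes or stem shares in clones may be partly set by that sort. The study's title concerns when secretory cells arise from Lgr5+ stem cells, and the comparisons address that question.

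Each mouse had its own hashtag antibody, and the clones and control cells of a mouse went into opposite pools, so that both pools held all 4 groups. Pool 1 held 3342 barcodes with 30278443 unique molecular identifiers (UMIs) and pool 2 held 2110 barcodes with 28050962 UMIs. After hashtag assignment and filtering, 1993 cells remained. The 48 h clones were thin, with 110 cells in all: 4, 15, 83 and 8 cells in mice 1, 2, 3 and 4, and 77566 to 298850 UMIs per mouse. The 72 h clones held 631 cells (40 to 326 per mouse, 813389 to 6370450 UMIs). The control samples held 586 cells in the 48 h mice (74 to 218, 1471640 to 5042193 UMIs) and 666 cells in the 72 h mice (77 to 261, 1950263 to 5186012 UMIs). The 83 clone cells of mouse 3 stood apart from those of the other 3 mice. Their median depth was 1841 UMIs, their top hashtag took a median of 48.6% of hashtag counts, against 87.2% to 94.2%, and 41 of the 83 had no class name.

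The cells fell into the known lineages of the crypt: 326 stem, 593 dividing, 191 secretory progenitor, 51 dividing secretory, 257 goblet, 71 Paneth, 34 enteroendocrine, 48 tuft and 247 enterocyte cells, with 175 cells left unnamed. The unnamed cells formed a cluster with Olfm4, Ifitm3 and H2-Eb1 among its leading genes but too few markers of any class, and had a Lgr5 UMI in 40.4% (clones, 99 cells, median 3965 UMIs) and 52.6% (control, 76 cells, median 11358.5 UMIs). Of the stem cells, 219 formed a cluster with Lgr5, Olfm4 and Pdgfa among its 10 leading genes, and 107 a cluster led by Clca3a1 and Zbtb16. Secretory progenitors had Dll1, a Notch ligand, and Spdef and Atoh1, transcription factors of the secretory lineage, among theirs. Lgr5 had a UMI in 85.1% of clone stem cells (149 of 175, 95% Wilson interval 79.1% to 89.7%, median 16155 UMIs) and in 80.1% of control stem cells (121 of 151, 73.1% to 85.7%, median 15657 UMIs). In enterocytes, which should lack it, the shares were 1.61% (1 of 62, median 24153 UMIs) and 2.16% (4 of 185, median 26477 UMIs). Goblet and Paneth products were found outside their cells. Muc2, the main gel-forming mucin, had a UMI in 50.8% of control enterocytes (94 of 185), and Defa24, a Paneth alpha-defensin, in 62.7% (116 of 185). Their counts over all cells therefore include free RNA. Clone stem and dividing cells had an Atoh1 UMI in 5.77% of cells (24 of 416, interval 3.91% to 8.44%, median 16149 UMIs) and control ones in 2.19% (11 of 503, 1.23% to 3.87%, median 16557 UMIs). In clone enterocytes it was 0 of 62, which allows up to 4.84% (11.1% for the 27 cells left without mouse 8), and in control enterocytes 2.70% (5 of 185, 1.16% to 6.17%). The intervals of the stem and dividing cells of the 2 gates did not overlap each other. Both overlapped that of the control enterocytes, which were deeper. Overlap is not a test, so whether Atoh1 in stem and dividing cells lay above background was not settled. These intervals and limits cover counting error only.

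The first comparison asks which cells the clones held at 48 h, beside control epithelium of the same mice. Secretory cells (Paneth, goblet, enteroendocrine, tuft and secretory progenitor cells together) made up 8.82% ± 11.1 of the clone cells and 38.7% ± 7.15 of the control cells (SD, n = 4 mice). The share was lower in the clones of 4 of 4 mice, with 0 of 4, 1 of 15, 3 of 83 and 2 of 8 cells in mice 1, 2, 3 and 4. In mice 1 and 4 the Wilson intervals (0% to 49.0% and 7.15% to 59.1%) held the control shares of 39.3% and 42.3%. In mice 2 and 3 their upper limits (29.8% and 10.1%) lay below the control shares of 44.6% and 28.4%. The difference of -29.8 percentage points gave p = 0.0286 in the exact two-sided permutation test, the smallest p that 4 against 4 allow. The exact sign-flip test within mice gave p = 0.125, the smallest that 4 pairs allow. Secretory progenitors made up 0.301% ± 0.602 of the clones and 14.7% ± 2.95 of control cells (SD, n = 4, exact p = 0.0286, adjusted p = 0.0952). The clones held 1 such cell of 110, from mouse 3. That class hung on the clustering. At resolution 0.6, with the Gaussian mixture, with variable genes chosen without those called within a class, with the 50% mitochondrial limit and with that limit and the 70% hashtag minimum together, no cluster took this name. At resolution 1.5 it went to 29 cells, against 191. Goblet and progenitor cells together, which do not need that boundary, made up 6.55% ± 12.3 of the clones and 29.3% ± 6.17 of control cells (SD, n = 4, -22.8 percentage points, exact permutation p = 0.0571). Goblet cells made up 6.25% ± 12.5 against 14.6% ± 3.88 (SD, n = 4), and the 2 goblet cells of the clones were both from mouse 4. The goblet difference was -4.86 percentage points without mouse 2 and -14.8 without mouse 4, against -8.38. No tuft cell was among the 110 clone cells, which allows a share of up to 2.73%, but up to 11.1% in the 27 cells left without mouse 3, beside 3.39% ± 3.45 in control (SD, n = 4). Stem cells made up 31.0% ± 17.1 of the clones and 6.90% ± 6.45 of control cells (SD, n = 4, exact permutation p = 0.0571, higher in 4 of 4 mice). Dividing cells made up 28.2% ± 7.91 and 30.1% ± 12.2 (SD, n = 4), with a difference of -6.74 to 2.78 percentage points when a mouse was left out. No single class passed the test after adjustment over the 10 classes, which with 4 against 4 a class cannot do alone. The secretory difference lost its call with a Gaussian-mixture hashtag assignment (28.4% ± 19.5 against 40.3% ± 15.9 in n = 4 mice, -11.9 percentage points, exact p = 0.429), which kept 155 cells of pool 2 and 16, 1, 9 and 79 clone cells of mice 1, 2, 3 and 4, and with mitochondrial shares up to 50% (-19.3 percentage points, exact p = 0.0571). Leaving out mouse 1, 2, 3 or 4 gave -26.7, -27.1, -31.5 and -34.0 percentage points, each with exact p = 0.1, the smallest that 3 against 3 allow.

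At 72 h the clones held secretory progenitors, goblet and Paneth cells in 4 of 4 mice and tuft cells in 3 of 4. Secretory cells made up 23.8% ± 13.2 of the clones and 35.1% ± 9.59 of control cells (SD, n = 4, exact permutation p = 0.229, lower in 3 of 4 mice, and a difference of -17.0 rather than -11.3 percentage points without mouse 6). Secretory progenitors made up 5.77% ± 3.23 and 8.58% ± 1.45, goblet cells 12.6% ± 10.3 and 17.4% ± 6.38, and Paneth cells 3.33% ± 3.00 and 4.68% ± 2.01 (SD, n = 4). Goblet and progenitor cells together differed by -7.60 percentage points (exact permutation p = 0.2, n = 4). The goblet difference ranged from -10.2 (without mouse 6) to -1.48 percentage points (without mouse 8) and the Paneth difference from -2.91 to -0.392 (the same mice). Enterocytes, the absorptive cells, made up 6.58% ± 2.77 of the clones and 16.7% ± 2.11 of control cells, lower in 4 of 4 mice (SD, n = 4, exact p = 0.0286, adjusted p = 0.286). Stem cells made up 29.6% ± 13.7 and 16.2% ± 9.82 (SD, n = 4, exact permutation p = 0.229). No class passed after adjustment, which a class alone at the smallest p cannot do.

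Between the clones of both times, secretory progenitors went from 0.301% ± 0.602 at 48 h to 5.77% ± 3.23 at 72 h in different mice (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.143). That test rests on the same class. Goblet and progenitor cells together differed by 11.8 percentage points (exact permutation p = 0.2 with n = 4). The difference in the secretory share was 15.0 percentage points (exact permutation p = 0.143 with n = 4), 9.62 without mouse 6, 2.00 with mitochondrial shares up to 50%, and of the other sign with the Gaussian mixture (-3.64) and with a top hashtag of at least 70% at that limit (-2.16). In the control cells of the same mice the secretory share differed by -3.56 percentage points (exact p = 0.571), and by -8.16 to -1.05 when a mouse was left out. The share of unnamed cells differed by -19.7 percentage points between the clones of both times (exact permutation p = 0.0286 with n = 4, adjusted p = 0.143), and by -12.1 without mouse 3, which held 41 of the 46 unnamed 48 h clone cells. The clone-control difference in secretory progenitors was -14.4 ± 3.52 percentage points at 48 h and -2.80 ± 2.72 at 72 h (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.143). Control cells took part in this, since their progenitor share was 14.7% ± 2.95 at 48 h and 8.58% ± 1.45 at 72 h (SD, n = 4, exact permutation p = 0.0571), while that of the clones differed by 5.47 percentage points. For goblet and progenitor cells together the change was 15.2 percentage points (exact permutation p = 0.114 with n = 4). The difference in the secretory share went from -29.8 ± 10.6 to -11.3 ± 12.3 (SD, n = 4, exact p = 0.0857). Without mouse 4 that last test gave 22.8 percentage points and exact p = 0.0286, against 18.6 with all mice.

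Over all 8 mice the clones held fewer secretory cells, 16.3% ± 13.9 against 36.9% ± 8.06 (SD, n = 8, exact permutation p = 0.00420, sign-flip p = 0.0156, lower in 7 of 8 mice). Of the 10 classes 4 passed after adjustment, in a test over all mice that was added later. Secretory progenitors (3.04% ± 3.63 against 11.6% ± 3.91, adjusted p = 0.0117), enterocytes (5.63% ± 4.35 against 14.2% ± 4.24, adjusted p = 0.0117) and dividing secretory cells (0.887% ± 1.04 against 3.20% ± 2.33, adjusted p = 0.0241) were fewer in the clones (SD, n = 8, exact permutation tests). Goblet and progenitor cells together differed by -15.2 percentage points (exact permutation p = 0.00777, n = 8). Stem cells (30.3% ± 14.4 against 11.6% ± 9.17, adjusted p = 0.0241, exact permutation test, n = 8) were more, in a class that also hung on the clustering. Exact sign flips within mice also called tuft cells (0.858% ± 1.28 against 3.19% ± 2.64, lower in 7 of 8 mice, adjusted p = 0.0313, and 0.0578 unpaired) and unnamed cells (16.9% ± 14.9 against 6.02% ± 2.96, higher in 8 of 8, adjusted p = 0.0313, and 0.0503 unpaired, SD, n = 8), which made 6 classes. The dividing secretory difference went from -2.32 to -1.46 percentage points without mouse 1, the tuft difference from -2.33 to -1.51 without mouse 2 and the unnamed difference from 10.9 to 6.59 without mouse 3. With the Gaussian-mixture assignment the secretory difference was -10.1 percentage points (exact permutation p = 0.228) and 0 classes passed. Without mouse 1, 2, 4 or 7, 2 classes passed.

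**Figure D1:**
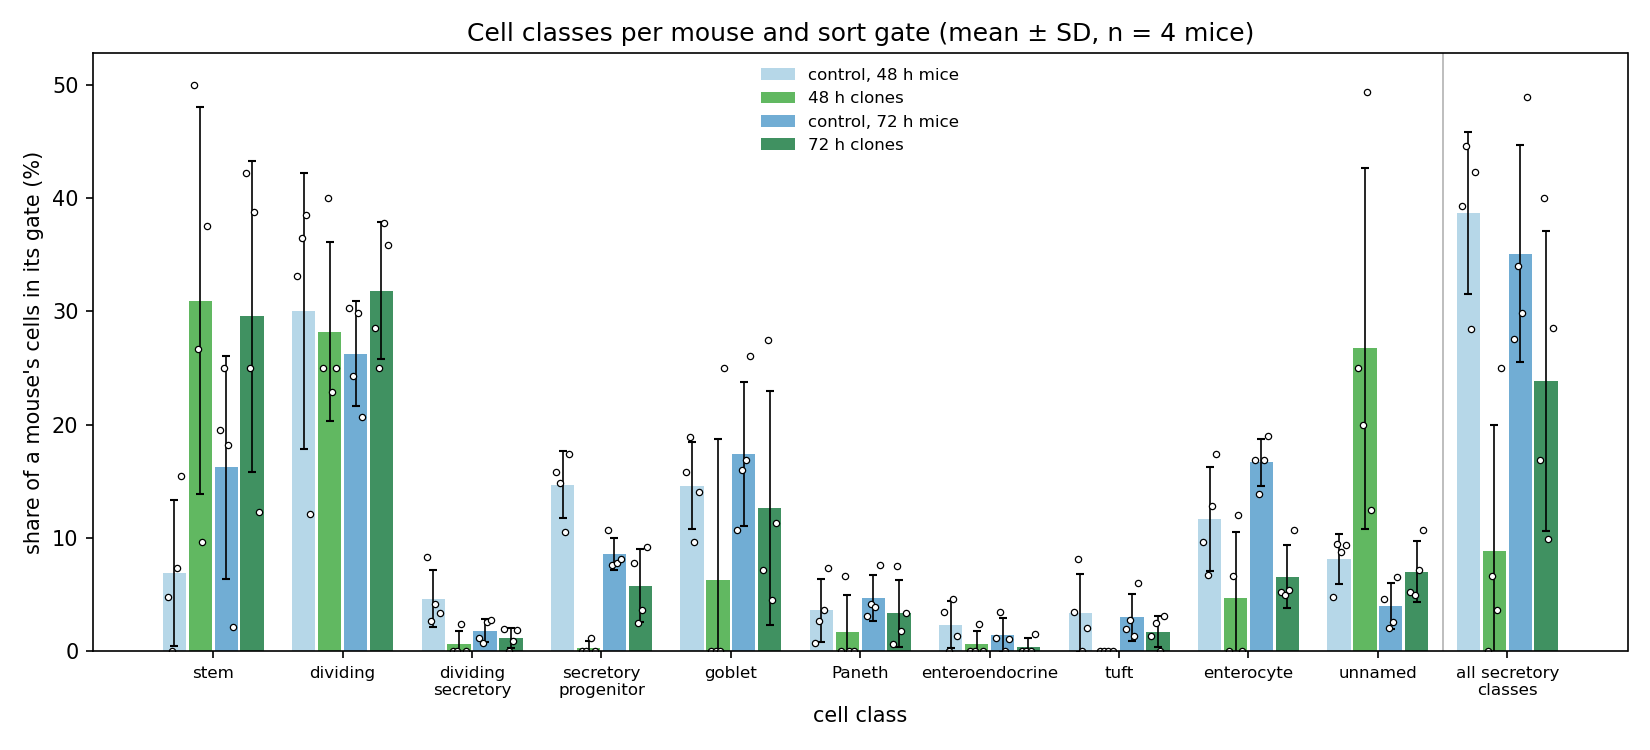
Share of cells per mouse (percent of the cells of that mouse and gate, y axis) in each class for the 48 h clones, 72 h clones and the control cells of both sets of mice; points are mice, bars are means and error bars are 1 SD with n = 4, cut at 0. The secretory share of the 48 h clones (mean 8.82%) lay below that of their control cells (38.7%), and that of the 72 h clones was 23.8%.

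Summed over all cells of a mouse, the genes called at 48 h with mouse as a block included 2 stem genes, higher in the clones, and 8 goblet, 5 enteroendocrine and 3 tuft genes, lower. As lists, none of these 4 held with an estimated correlation (adjusted p = 0.334 for stem, 0.486 for goblet and tuft and 0.823 for enteroendocrine genes). Axin2, a Wnt target, was higher by 1.02 ± 0.19 on the log2 scale (SE, adjusted p = 0.0152) and Olfm4, a crypt base marker, by 1.05 ± 0.22 (adjusted p = 0.0277), both in 4 of 4 mice. Lgr5 (chromosome 10, 115450311 to 115587780, mm10) reached 1.33 ± 0.33 (adjusted p = 0.0688), higher in 3 of 4 mice. These and the values that follow are from edgeR with mouse as a block. Zg16, a goblet lectin (ENSMUSG00000049350, chromosome 7, 127050156 to 127087328), fell by 3.28 ± 0.50, from 4270 ± 2206 to 417 ± 334 CPM (counts scaled to library size, SD, n = 4 mice, adjusted p = 0.00517). Muc2 fell by 2.97 ± 0.48 and Tff3, a goblet trefoil peptide, by 2.60 ± 0.55. Atoh1 (ENSMUSG00000073043, chromosome 6, 64729125 to 64731245), the transcription factor that sets the secretory fate, fell by 2.29 ± 0.46 (adjusted p = 0.0260, 14.6 ± 18.8 against 78.6 ± 23.7 CPM, n = 4), in 4 of 4 mice. Dclk1, a tuft cell kinase, fell by 4.52 ± 0.80, and Chga, the hormone-granule protein chromogranin A, fell by 6.06 ± 0.64.

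With the block, 14 genes rose and 81 fell of 10606 tested. Of the 81, 75 were lower in 4 of 4 mice, and 47 did not overlap between groups. Without the block, the analysis fixed beforehand, edgeR called 0 genes (1271 at an unadjusted p under 0.05, lowest adjusted p 0.113, for Zg16), while DESeq2 called 63, of which 33 were among the 95. Genes without overlap made up 9.05% of those tested, where chance gives 2.86% for samples of like depth. The clone sums were shallower (77566 to 298850 UMIs) than the control sums (1471640 to 5042193), which alone can part genes with few counts. The excess therefore cannot be read as a clone-control difference. Among the 81 were 8 goblet genes (with Spink4, Fcgbp, Ern2, Clca1 and Agr2), 3 secretory progenitor genes (Atoh1, Creb3l1, Hepacam2), 5 enteroendocrine genes (Chga, Chgb, Gcg, Neurod1, Tac1), and 3 tuft genes (Dclk1, Rgs13, Kctd12). A further 7 were genes of protein folding in the endoplasmic reticulum, among them the chaperones Hspa5 (fell by 0.95 ± 0.17) and Hsp90b1 (fell by 0.82 ± 0.19). Among called genes with an average log2 CPM of at least 4 and no overlap between groups, others that fell most were Hid1 (fell by 3.40 ± 0.74) and Syt7 and Sytl2 (fell by 3.10 ± 0.57 and 2.41 ± 0.44), which serve vesicle traffic and secretion, Pde2a (fell by 3.91 ± 0.65), Kcnk6 and Cracr2a. By the same limits, those that rose most beside Axin2 were Pdgfa (1.16 ± 0.26), a ligand of crypt mesenchyme, Sorbs2 (1.11 ± 0.25), Epb41l4aos, Cftr (0.88 ± 0.20), the crypt chloride channel, Nlrp6, Sdc4 and Zfp36l2. These calls hung on single mice. Without mouse 1 there were 16 (8 higher, 8 lower) and without mouse 2 there were 7, with no gene higher. Of 35 called genes followed under every alternative, 26 lost their call without mouse 1 and 32 without mouse 2, Axin2 and Olfm4 both times (adjusted p = 0.105 and 0.299, then 0.261 and 0.353), as did Muc2 and Atoh1. Zg16 lost it without mouse 2 (adjusted p = 0.0916), and 2 of the 35, Chgb and Gcg, kept it in the blocked fit whichever mouse was left out. Without mouse 1 Hsp90b1 stood at -0.51, without mouse 2 Pdgfa at 0.62, without mouse 3 Chga at -10.04, and without mouse 4 Dclk1 at -9.01 and Hid1 at -9.15. For Chga, Dclk1 and Hid1 the clones that remained held no UMI, so the size of these folds is not measured. The count was 222 without mouse 3, 186 without mouse 4 and 180 without mouse 6, and 48 with sums of at least 10 cells.

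At 48 h camera, at a preset correlation, called 10 of the gene lists fixed beforehand. None of the 10 calls held with an estimated correlation, where adjusted p was 0.334 for the stem list and 0.463 to 0.579 for the other 9. All 13 stem genes were higher (median 0.85, 8 passed adjusted over the list alone, 0 over all genes, adjusted p = 3.28e-09). So were 11 of 12 Wnt targets (median 0.56, 4 adjusted over the list alone, adjusted p = 0.000133) and 4 of 6 Notch targets with Hes1 (median 0.52, 2, adjusted p = 0.0212). Higher too were 14 of 20 genes of the G1/S phase (median 0.49, 0, adjusted p = 0.000149) and 7 of 7 MHC class II genes, Cd74 and H2-Ab1 among them (median 0.44, 0, adjusted p = 0.000715). All 20 goblet genes were lower (median -1.66, 10 adjusted over the list alone, adjusted p = 1.07e-07). So were 10 of 11 secretory progenitor genes (median -1.68, or -1.29 with Neurog3, which had no UMI in the clones, at its limit, 4, adjusted p = 0.00683) and 19 of 19 tuft genes (median -3.45, or -2.54 with 5 genes at their limits, 0, adjusted p = 1.26e-05). Lower too were 18 of 18 protein folding genes (median -0.77, 11, adjusted p = 5.78e-05) and 23 of 24 genes of the G2/M phase, with Top2a and Mki67 (median -0.64, 0, adjusted p = 0.000112). The G1/S call was lost without mouse 2 (median 0.056, adjusted p = 0.0694) and the secretory progenitor call without mouse 3 (median -1.84, adjusted p = 0.115). The MHC class II call was lost without mouse 1 (median 0.19, adjusted p = 0.0858) and the Notch call without mouse 1, 2 or 4 (medians 0.54, 0.36 and 0.45, adjusted p = 0.0858, 0.0694 and 0.0857). Medians of calls that were kept also moved by over 1.5 times: goblet to -2.95 without mouse 4, G2/M to -0.38 without mouse 1 and -1.43 without mouse 3, Wnt targets to 0.36, 0.24 and 0.945 without mouse 1, 2 or 3, and MHC class II to 0.72 without mouse 3. The enteroendocrine list, 17 of 19 genes lower (median -1.06, adjusted p = 0.129), passed with the block (median -2.07, adjusted p = 0.00759, 0.539 with an estimated correlation). It also passed without the block when mouse 2, 7 or 8 was left out (medians -1.79, -1.70 and -1.11, adjusted p = 0.00131, 0.0415 and 0.0260) and with mitochondrial shares up to 50% (-1.58, adjusted p = 0.00923), and its median ranged from -6.26 (without mouse 3) to -0.66 (without mouse 1). Mouse 3 held the 2 enteroendocrine cells of the 48 h clones, so the -6.26 lies near the floor and gives a direction only.

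At 72 h the genes called with the block included 10 stem genes, higher in the clones, and 13 Paneth, 9 mature enterocyte, 8 tuft and 7 enteroendocrine genes, lower. As lists, the stem and Paneth genes held with an estimated correlation (adjusted p = 0.0269 and 0.0332), the other 3 did not (0.273 to 0.289), and none did with the block as well. With mouse as a block, Lgr5 (ENSMUSG00000020140) rose by 1.29 ± 0.23 on the log2 scale (SE, adjusted p = 0.00460, 117 ± 40.2 against 49.5 ± 15.8 CPM, SD, n = 4 mice) and Olfm4 (ENSMUSG00000022026, chromosome 14, 79984081 to 80023139) by 1.01 ± 0.21 (adjusted p = 0.0172). Sp5, a Wnt target, rose by 1.37 ± 0.26, and Cd44 and Ephb3, Wnt targets of the crypt base, by 0.92 ± 0.16 and 0.89 ± 0.16. These rises may be partly set by the sort, since the gates may have selected on the EGFP of the Lgr5 allele. Sis, the brush border sucrase-isomaltase (ENSMUSG00000027790, chromosome 3, 72888557 to 72967863), fell by 1.68 ± 0.41 (adjusted p = 0.0362, 35.6 ± 9.07 against 113 ± 53.5 CPM, n = 4). The peptidase Enpep fell by 1.46 ± 0.28 and Mttp, which loads lipid onto lipoproteins, by 1.11 ± 0.24. Among Paneth genes, Lyz1, lysozyme, fell by 2.17 ± 0.38 (adjusted p = 0.00387, 346 ± 288 against 1598 ± 1314 CPM, n = 4), and the alpha-defensin Defa36 (ENSMUSG00000094662, chromosome 8, 21427411 to 21428391) by 4.08 ± 0.34, both in 4 of 4 mice. Muc2 and Atoh1 did not pass at 72 h (-0.39 ± 0.41 and -0.50 ± 0.20).

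In that blocked edgeR fit 79 genes rose and 119 fell, 71 and 89 of them in 4 of 4 mice. Of these, 25 were also called at 48 h, 23 in the same direction. Without the block edgeR called 0 genes (842 at an unadjusted p under 0.05, lowest adjusted p 0.0926) and DESeq2 called 8. These were Esr1, Bex4, Cep112, Mcc and Rgcc higher and Cdkn1a, Glod5 and Mkrn1 lower, and 7 were among the 198. Those 8 were chosen after their values were seen. Of the 79, 10 were stem genes (Ascl2, Axin2, Cdca7, Lgr5, Olfm4, Rgmb, Slc12a2, Smoc2, Soat1 and Sox9) and 8 Wnt targets, with Rnf43 beside those named. Hes1, a Notch target, rose by 0.80 ± 0.18. Bex4 (1.18 ± 0.17), Pdgfa (1.13 ± 0.20), Cdc42ep1 (0.95 ± 0.23), Cd320 (0.94 ± 0.19) and Cdca7 (0.89 ± 0.15) completed the 10 that rose most among called genes with an average log2 CPM of at least 4 and no overlap between groups. Of the 119, 13 were Paneth, 9 mature enterocyte, 8 tuft and 7 enteroendocrine genes, and 3 protein folding genes. By the same limits the 10 that fell most were AY761184 (fell by 4.45 ± 0.50), Defa36 and Gm7861 (fell by 3.65 ± 0.33) of the alpha-defensin locus, Dpep1 (fell by 1.78 ± 0.33), Sis, Enpep, Maf, Cst6 (fell by 1.39 ± 0.27), Chp2 and Mttp. Cdkn1a, a p53 target, fell by 0.88 ± 0.19. The number of genes was 43 without mouse 5 (13 higher), 65 without mouse 7 (13 higher) and 37 without mouse 8 (4 higher), against 79 higher. Lgr5 lost its call without each of them (1.20, 1.09 and 1.14, adjusted p = 0.0847, 0.0693 and 0.149), Olfm4 without mouse 7 or 8 (0.84 and 0.75, adjusted p = 0.174 and 0.329) and Lyz1 without mouse 5 (-1.61, adjusted p = 0.0589). Of 46 called genes that were followed, 14 kept their call in the blocked fit whichever mouse was left out, among them Esr1, Bex4, Defa36 and Chga. Without the block edgeR called none of them, and DESeq2 called Esr1 and Bex4 but not Defa36 or Chga. The number was 333 without mouse 3 and 402 without mouse 6, and over 1.5 times as large without mouse 2. Genes without overlap made up 4.83% of those tested.

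Esr1, which encodes estrogen receptor alpha (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614), was higher in the clones of 4 of 4 mice at each time and was named after its values were seen. With the block it rose by 3.54 ± 0.59 at 48 h (adjusted p = 0.00842, 23.1 ± 24.3 against 1.82 ± 0.935 CPM), or 2.68 without mouse 2 (adjusted p = 0.515), and by 2.73 ± 0.34 at 72 h (adjusted p = 9.89e-05, 12.8 ± 5.95 against 2.02 ± 0.665 CPM, SD, n = 4 mice). The estrogen receptor is also the source of the hormone-binding part of CreERT2, whose coding sequence lies in the Lgr5 allele of these mice.

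At 72 h camera called 13 lists at the preset correlation. With an estimated correlation the stem, Wnt and Paneth calls held (adjusted p = 0.0269, 0.0312 and 0.0332), that for the Notch targets was 0.0598 and those for the other lists 0.152 to 0.513. With the block as well, none held (adjusted p = 0.0703 for those 4). All 13 stem genes were higher (median 0.80, 12 adjusted over the list alone, 0 over all genes, adjusted p = 1.28e-20). So were 12 of 12 Wnt targets (median 0.82, 9, adjusted p = 3.01e-13) and 6 of 6 Notch targets (median 0.44, 2, adjusted p = 6.43e-05). Higher too were 20 of 20 G1/S genes (median 0.40, 0, adjusted p = 1.78e-06) and 7 of 7 MHC class II genes (median 0.37, 0, adjusted p = 0.00593). Lower were 18 of 18 Paneth genes (median -2.15, 9, adjusted p = 2.08e-18) and 19 of 19 tuft genes (median -1.14, 0, adjusted p = 1.84e-06). For the defensins much of this came from the control cells of mice 7 and 8, where Defa30 stood at 5899 and 1405 CPM, against 27.4 and 44.8 CPM in those of mice 5 and 6. In mouse 5 the clones were not lower in Defa21 (32.8 against 21.8 CPM), Defa22 (32.8 against 23.2) or Defa30 (28.8 against 27.4). The Paneth share of these mice was 3.33% in clones and 4.68% in control cells. Lower too were 16 of 19 enteroendocrine genes (median -0.75, 0, adjusted p = 3.19e-05) and 15 of 18 mature and 9 of 10 immature enterocyte genes (medians -1.08 and -0.49, 8 and 0, adjusted p = 1.94e-05 and 0.00182). The same held for 20 of 20 goblet genes (median -0.52, 0, adjusted p = 0.00110), 18 of 18 protein folding genes (median -0.39, 0, adjusted p = 1.72e-08) and 20 of 20 genes of oxidative phosphorylation (median -0.19, 0, adjusted p = 1.06e-09). The lists of BMP targets, interferon response, p53 targets, fetal-like regeneration and M cells were not called at 48 h (medians -0.17, 0.12, -0.081, -0.067 and -0.52, adjusted p 0.506 to 0.947) or at 72 h (-0.29, -0.24, -0.11, -0.14 and -0.65, adjusted p 0.0897 to 0.520). Exceptions at 72 h were M cell genes with the block (adjusted p = 0.0445) and without mouse 6 (-0.86, adjusted p = 0.0412), interferon genes without mouse 6 (-0.44, adjusted p = 0.0470) and BMP targets without mouse 4 or 8 (-0.31 and -0.43, adjusted p = 0.0430 and 0.0426). Leaving out a mouse gave medians of -0.36 to -0.036, -0.33 to 0.27, -0.20 to 0.12, -0.88 to 0.19 and -0.997 to 0.056 for these 5 lists at 48 h, and -0.44 to -0.16, -0.44 to 0.13, -0.19 to -0.089, -0.23 to 0.031 and -0.86 to -0.36 at 72 h. The Paneth list was not called at 48 h (median 0.78, adjusted p = 0.545), nor was the mature enterocyte list, whose median was 0.44 while its test pointed down (adjusted p = 0.159). Leaving out a mouse turned both medians (Paneth -0.80 without mouse 2, mature enterocyte -1.41 without mouse 3), and the mature enterocyte list passed, lower, without mouse 3 (adjusted p = 0.000426), at the 50% limit (median 0.19, adjusted p = 0.0428), at the 70% hashtag minimum (-1.32, adjusted p = 0.000141) and with both (-1.53, adjusted p = 7.09e-05). The goblet call was lost without mouse 7 or 8 (medians -0.40 and -0.38, adjusted p = 0.608 and 0.486). The MHC class II call was lost without either of them (0.31 and 0.086, adjusted p = 0.107 and 0.299) and the immature enterocyte call without mouse 7 (-0.30, adjusted p = 0.0938). Kept calls moved to -1.07 (goblet) and 0.58 (MHC class II) without mouse 6, and the enteroendocrine median to -0.38 without mouse 5 and -2.12 without mouse 8.

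**Figure D2:**
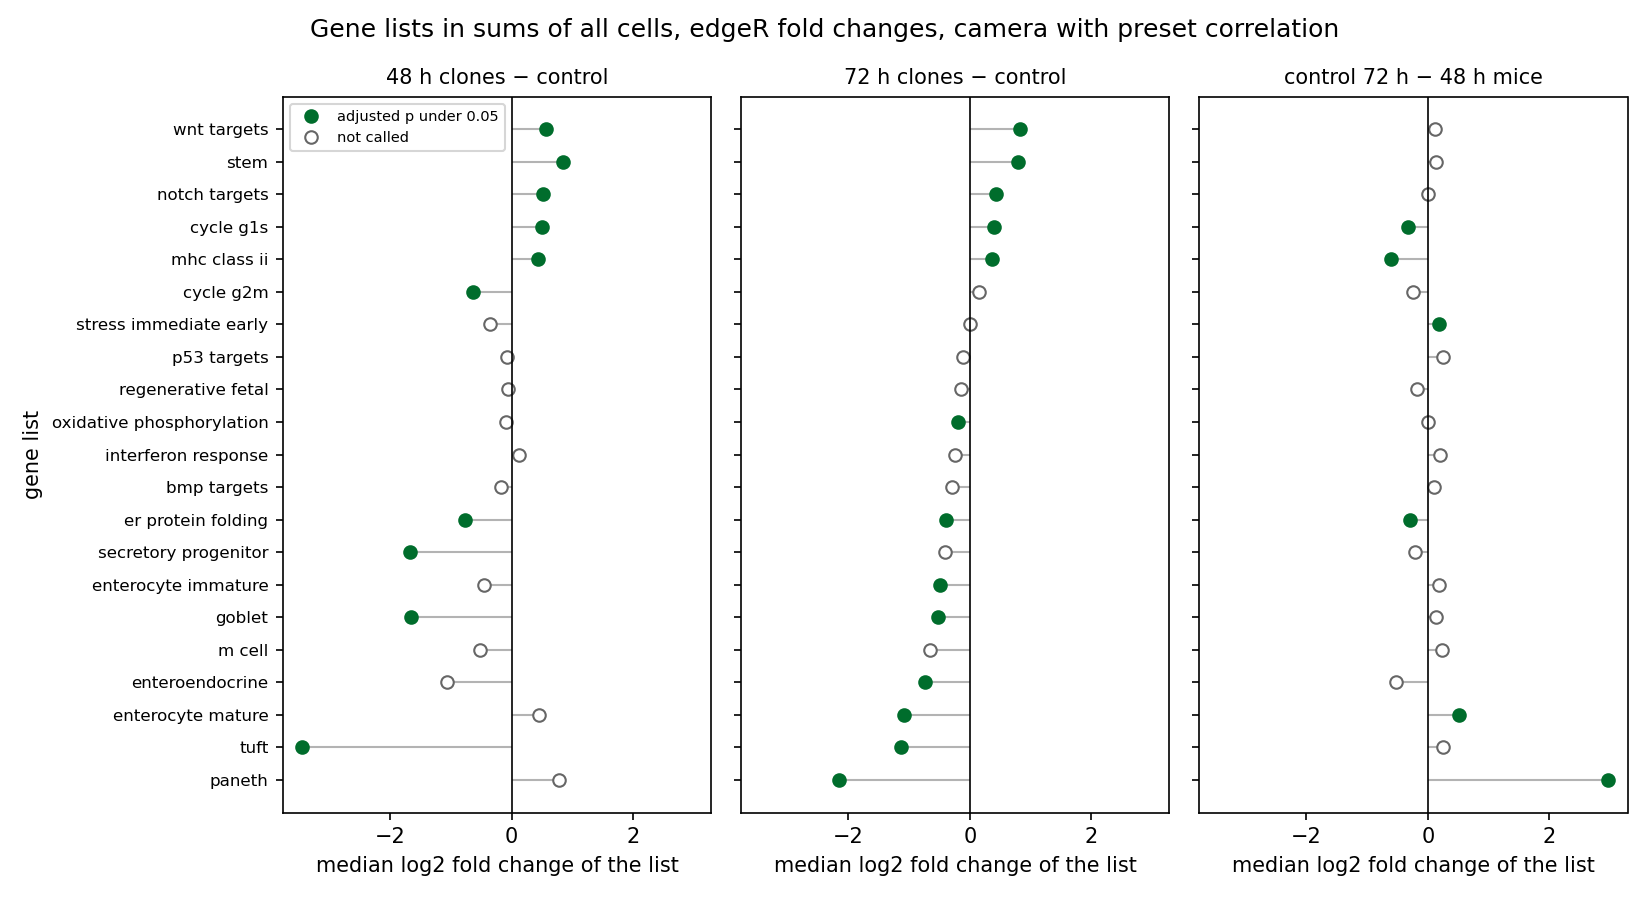
Median log2 fold change of the tested members of each gene list (x axis) over all cells, for clones against control cells of the same mice at 48 h and at 72 h and for control cells of the 72 h mice against those of the 48 h mice. Filled points had a camera adjusted p under 0.05. Stem genes were higher at both times (medians 0.85 and 0.80), goblet genes were lower (-1.66 at 48 h and -0.52 at 72 h), and Paneth genes were lower at 72 h (-2.15) and higher in control cells of the 72 h mice (2.97). With an estimated correlation the stem call at 48 h and the goblet calls were lost (adjusted p = 0.334, 0.486 and 0.513), and those for stem and Paneth genes at 72 h (0.0269 and 0.0332) and for Paneth genes between control cells (0.00905) held, though none held at 72 h with the block as well (adjusted p 0.0703 or more).

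Between the clones of both times edgeR called 0 genes (664 at an unadjusted p under 0.05), and DESeq2 called 1, Zg16, which was 3.15 higher on the log2 scale at 72 h in edgeR (adjusted p = 0.239). Camera called 7 lists. None held with an estimated correlation (adjusted p 0.295 to 0.989). The goblet genes were higher at 72 h in 20 of 20 cases (median 1.16, 1 adjusted over the list alone, adjusted p = 8.49e-06). So were 19 of 19 tuft genes (median 2.84, or 1.62 with 5 genes at their limits, 0, adjusted p = 0.0150), 23 of 24 G2/M genes (median 0.59, 0, adjusted p = 0.000254) and 11 of 13 stress and immediate early genes (median 0.56, 4, adjusted p = 0.00178). Lower were 7 of 7 MHC class II genes (median -0.74, 0, adjusted p = 5.57e-07), 14 of 20 G1/S genes (median -0.27, 0, adjusted p = 0.00111) and 14 of 20 oxidative phosphorylation genes (median -0.061, 0, adjusted p = 0.00109). The tuft call was lost without mouse 2, 3, 4, 6 or 8 (medians 3.47, 3.08, 2.54, 2.70 and 1.68, adjusted p = 0.0733, 0.0711, 0.133, 0.0616 and 0.0697). The G1/S call was lost without mouse 2 or 6 (-0.063 and -0.15, adjusted p = 0.0847 and 0.0525), the stress call without mouse 3 (0.45, adjusted p = 0.0754) and the oxidative phosphorylation call without mouse 1 (-0.0050, adjusted p = 0.0534). Kept calls moved to 0.65 and 2.52 (goblet, without mouse 2 or 4), 1.18 and 0.35 (G2/M, without mouse 3 or 4), -1.14 (MHC class II, without mouse 8) and -0.020, 0.0030 (with the test still down), -0.018 and -0.16 (oxidative phosphorylation, without mouse 5, 6, 7 or 8).

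The control cells of the 72 h mice were set against those of the 48 h mice to show how far the mice themselves differed. They differed most in alpha-defensins, the antimicrobial peptides of Paneth cells. All 9 genes called by edgeR were higher in the 72 h mice, and 6 of them lie in the defensin cluster on chromosome 8. These were Defa5 (6.19 ± 0.87 on the log2 scale, SE, adjusted p = 0.0140), Defa34 (6.01 ± 0.93, 0.0256), Defa23 (6.28 ± 1.11), AY761184 (5.75 ± 1.05), Defa36 (5.56 ± 1.01) and Gm7861 (3.54 ± 0.61), each of the last 4 with adjusted p = 0.0431. Defa36 stood at 1113 ± 958 against 17.6 ± 7.64 CPM (SD, n = 4), with 128 and 454 CPM in mice 5 and 6 (pool 1) and 1930 and 1939 CPM in mice 7 and 8 (pool 2). Of the 6, Defa36 and AY761184 lay above all 48 h mice in 4 of 4 mice, while Defa5, Defa34 and Gm7861 of mouse 5 lay within the range of the 48 h mice. Defa23 stood at 1.00 and 2.40 CPM in mice 5 and 6, against 0 to 1.58 CPM in the 48 h mice, and at 271 and 115 CPM in mice 7 and 8. Defa21, Defa22 and Defa30, not called here, were high in mice 7 and 8 alone. The others were Clps, pancreatic colipase (3.48 ± 0.62), the carboxylesterase Ces2a (1.24 ± 0.22) and Ilvbl (0.64 ± 0.12). All 18 Paneth genes were higher (median 2.97, 2 over all genes and 15 adjusted over the list alone, camera adjusted p = 2.53e-35, and 0.00905 with an estimated correlation). Lyz1 stood at 3.01 ± 0.81 (adjusted p = 0.489). The Paneth share itself was 4.68% ± 2.01 against 3.61% ± 2.80 of cells (SD, n = 4, exact permutation p = 0.486).

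The same camera test called 5 further lists, which with an estimated correlation had adjusted p of 0.120 to 0.909. It put the stress and immediate early genes higher in the 72 h mice (11 of 13, median 0.19, 1 adjusted over the list alone, adjusted p = 0.000996) and mature enterocyte genes too (15 of 18, median 0.51, 0, adjusted p = 0.0352). MHC class II genes were lower (7 of 7, median -0.61, 1, adjusted p = 7.42e-10), as were G1/S genes (20 of 20, median -0.33, 0, adjusted p = 0.000280) and protein folding genes (15 of 18, median -0.30, 0, adjusted p = 7.85e-05). The gene count was 0 without mouse 1, 3 or 4, without the pool term, with the Gaussian mixture and with sums of at least 10 cells, and 2, 1, 18 and 53 without mouse 2, 7, 5 or 8. DESeq2 called 19, and 575 genes had an unadjusted p under 0.05 in edgeR. The stress call was lost without mouse 1 (median 0.16, adjusted p = 0.0805), the protein folding call without mouse 6 (-0.12, 0.101). The G1/S call was lost without mouse 1, 3 or 8 (-0.22, -0.17 and -0.25, adjusted p = 0.174, 0.112 and 0.0518), and the mature enterocyte call without mouse 2, 5, 7 or 8 (0.44, 0.36, 0.44 and 0.47, adjusted p = 0.185, 0.0561, 0.269 and 0.314). Where the call was kept, the G1/S median moved to -0.18 without mouse 6 and the protein folding median to -0.19 without mouse 5 and -0.50 without mouse 8. Enteroendocrine genes (median -0.523, camera adjusted p = 0.0823) passed, lower, without mouse 2, 4, 6 or 8 and at the 50% limit. Their medians were then -0.97, -0.754, -0.761, -0.925 and -0.622 (camera adjusted p 7.32e-14 to 0.0304). G2/M genes passed, lower, without mouse 4 or 7 (-0.476 and -0.494). Stem and Wnt genes passed without mouse 8, and oxidative phosphorylation genes without mouse 6.

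The change of the clone-control difference from 48 h to 72 h again set the alpha-defensins apart. With the block, edgeR called 10 genes. Chgb, a granin of enteroendocrine cells, changed by 2.82 ± 0.41 on the log2 scale. The other 9, of the defensin cluster, changed the other way, from -3.69 ± 0.60 for Defa21 to -7.85 ± 0.69 for Defa34, with Defa36 at -6.76 ± 0.72 (adjusted p = 8.15e-05). Without the block edgeR called 0 genes (554 at an unadjusted p under 0.05) and DESeq2 called 2, Defa34 and Defa36. In clones against control, Defa36 rose by 2.68 ± 0.57 at 48 h with the block (adjusted p = 0.0299), though in 2 of 4 mice only, and was lower at 72 h in 4 of 4 mice. Without mouse 2, 2 genes were called and all 9 defensin calls were lost. The clones of mouse 2 held 1354 CPM of Defa36, with 341 Defa36 UMIs in 1 Paneth cell. A lost call does not show that these genes were no longer lower. Chgb was lost without mouse 3 (8.19, adjusted p = 0.373) or 8 (3.56, adjusted p = 0.475), and Defa36 at 48 h without mouse 2 (0.54, adjusted p = 0.898). Without mouse 3 the 48 h clones held no UMI of Chgb, so the size of the 8.19 is not measured. The blocked count was 37 without mouse 4 and 18 without mouse 5. By list, camera called 6 changes, of which none held with an estimated correlation (adjusted p 0.905 to 0.975). It put goblet genes (20 of 20, median 1.11, adjusted p = 2.33e-05) and secretory progenitor genes (10 of 11, median 1.33, or 0.89 with Neurog3 at its limit, adjusted p = 0.0327) higher relative to control at 72 h than at 48 h. Higher too were tuft genes (18 of 19, median 2.50, or 1.48 with 5 genes at their limits, adjusted p = 0.0193) and G2/M genes (23 of 24, median 0.85, adjusted p = 2.54e-05). Lower were Paneth genes (14 of 18, median -2.74, 3 adjusted over the list alone, adjusted p = 6.88e-07) and oxidative phosphorylation genes (13 of 20, median -0.074, adjusted p = 0.000552). In the other 5 lists no gene passed adjusted over the list alone. The secretory progenitor call was lost without mouse 1 or 3 (1.02 and 1.24, adjusted p = 0.0625 and 0.325) and the tuft call without mouse 2, 4 or 6 (2.27, 2.13 and 2.13, adjusted p = 0.498, 0.238 and 0.0591). The Paneth median was -0.34 without mouse 2 (adjusted p = 0.000649) and 0.17 with the top hashtag at 70% or more, where the test still pointed down (adjusted p = 0.0196). Other kept calls moved to 0.71, 0.505, 2.42 and 0.52 (goblet, without mouse 1, 2, 4 or 6), 1.55 and 0.45 (G2/M, without mouse 3 or 5) and -0.040, -0.13, -0.0068 and -0.11 (oxidative phosphorylation, without mouse 4, 6, 7 or 8).

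**Figure D3:**
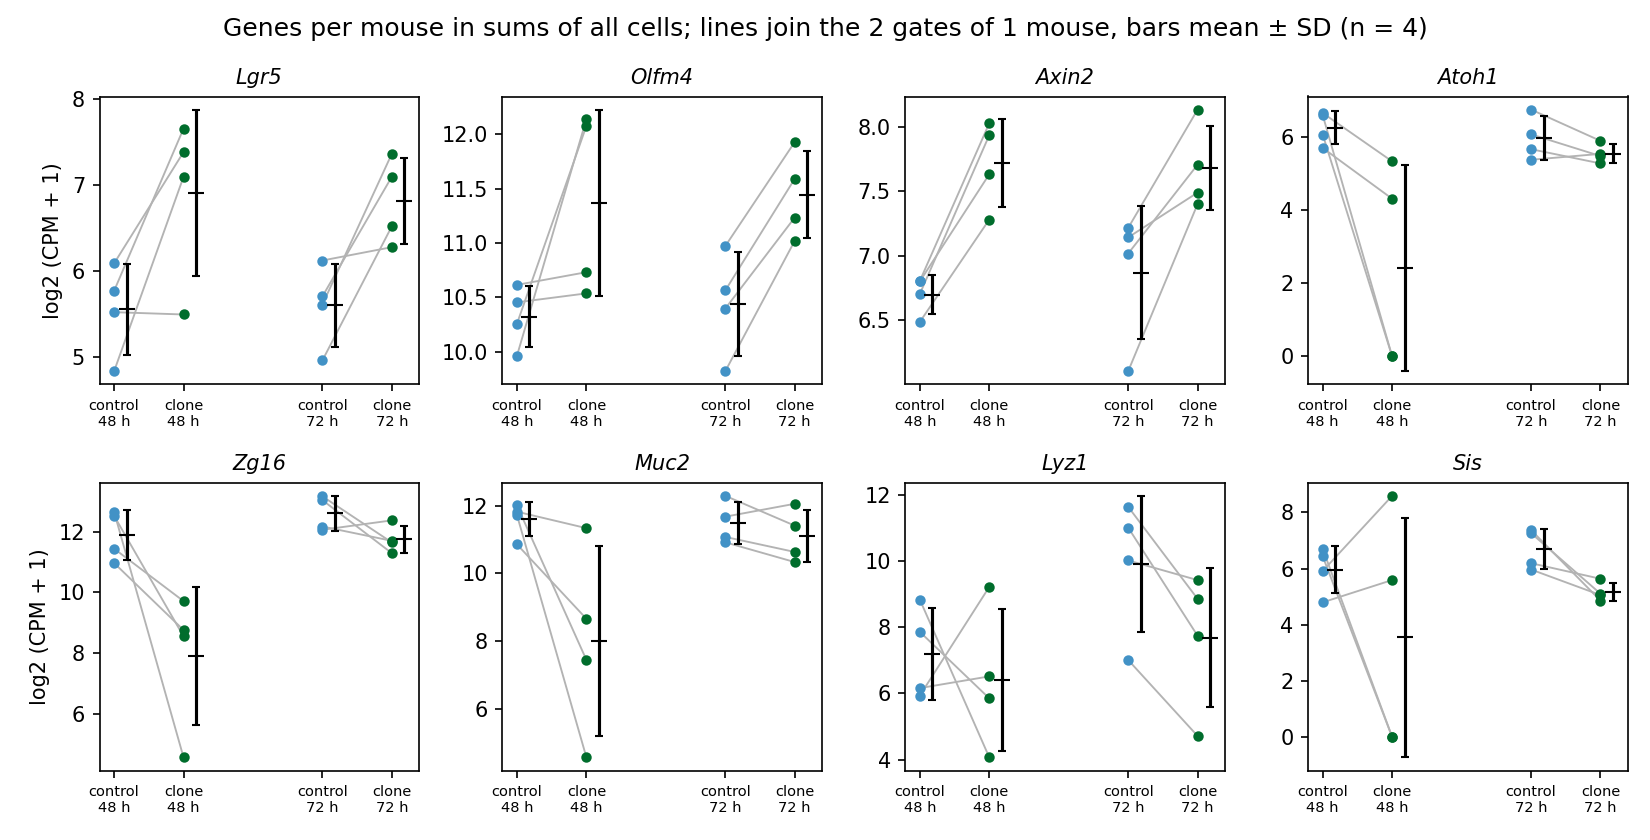
Lgr5, Olfm4, Axin2, Atoh1, Zg16, Muc2, Lyz1 and Sis per mouse in sums of all cells (y axis, log2 of CPM plus 1). Points are mice, lines join the clones and control cells of 1 mouse, and bars are the mean and 1 SD with n = 4 per group. Zg16 stood at a mean of 417 CPM in the 48 h clones and 4270 CPM in their control cells, and Lyz1 at 346 CPM in the 72 h clones and 1598 CPM in theirs.

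Within a single class, clones and control cells could be compared at 72 h alone. In dividing cells of the clones, 13 of 13 stem genes were higher than in dividing control cells (median 0.56, camera adjusted p = 6.98e-09, and 0.219 with an estimated correlation). So were 11 of 12 Wnt targets (median 0.66, adjusted p = 4.14e-08, and 0.0958 with an estimated correlation). In dividing cells with the block, Lgr5 rose by 1.15 ± 0.19 on the log2 scale (SE, adjusted p = 0.00173), Olfm4 by 0.58 ± 0.06, Sp5 by 1.19 ± 0.26, Bex4 by 0.93 ± 0.16, Rgcc by 1.68 ± 0.33 and Timp3 by 1.30 ± 0.24. Here too the gates may have selected on the EGFP of the Lgr5 allele. Lgals3, which rises as enterocytes mature, fell by 0.94 ± 0.15 and Slc28a3 by 1.79 ± 0.34. Mature enterocyte and oxidative phosphorylation genes were lower in dividing cells (medians -0.66 and -0.16, adjusted p = 0.0450 and 0.000601). In stem cells the stem, Wnt and MHC class II lists were higher (medians 0.090, 0.25 and 0.43, adjusted p = 0.0385, 0.0267 and 0.0385) and the BMP target list lower (median -0.51, adjusted p = 0.0385). None of these 6 held with an estimated correlation (adjusted p 0.344 to 0.831). In stem cells the genes Lgr5, Olfm4 and Axin2 did not pass (0.50 ± 0.18, 0.019 ± 0.050 and -0.026 ± 0.14 with the block). Sox4 rose by 0.62 ± 0.13 and Midn by 1.84 ± 0.51. In goblet cells Guca2b, the peptide uroguanylin, rose by 0.83 ± 0.15 and Lpgat1 by 1.23 ± 0.29. Samd9l, Mxd1 and S100a6 fell by 1.40 ± 0.32, 1.27 ± 0.31 and 0.60 ± 0.15. The blocked edgeR fits called 68 genes in dividing, 85 in stem and 9 in goblet cells, with 2, 1 and 1 residual degrees of freedom. With mitochondrial shares up to 50% the counts were 160, 0 and 65, so that all stem calls, Sox4 and Midn among them, were lost. The dividing count was 25 without mouse 5, 192 without mouse 6 and 40 without mouse 8, and 159 with the top hashtag at 70% or more, and the goblet count was 35 with both limits. Without the block edgeR called 0 in each (531, 277 and 132 at an unadjusted p under 0.05), as did DESeq2.

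Between the control cells of both sets of mice, enterocytes of the 72 h mice were higher in stress and immediate early genes. Hspa1a and Hspa1b, heat shock proteins, and Fosb (1.22 ± 0.20 on the log2 scale, SE, adjusted p = 0.0345) and Btg2 (1.16 ± 0.18, adjusted p = 0.0223) were the 4 genes edgeR called there, and DESeq2 called 2. The stress list was higher in enterocytes (11 of 13, median 0.61, adjusted p = 4.19e-08), dividing cells (13 of 13, median 0.41, adjusted p = 0.00136) and goblet cells (10 of 11, median 0.30, adjusted p = 0.0104), and the MHC class II list was lower in all 3 (medians -0.58, -0.51 and -0.70, adjusted p = 0.000226, 0.00136 and 0.00129). With an estimated correlation adjusted p was 0.579 to 0.867 for these 6. EdgeR called 0 genes between these controls in dividing, goblet and secretory progenitor cells (896, 227 and 319 at an unadjusted p under 0.05), and DESeq2 called 64, 0 and 2. In enterocytes 328 genes had an unadjusted p under 0.05, and none was called without the pool term or with mitochondrial shares up to 50%, and 2 without mouse 7.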

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

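The tests of the alpha-defensins, those of the 48 h secretory share and those of Esr1 other than the test of the CreERT2 allele were chosen after the result was seen, while that test and the splits of the samples were set down before theirs was.

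Esr1 was higher in clones than in control cells at both times. Within stem cells at 72 h its log2 fold change was 2.22 (SE 0.588, adjusted p = 0.803), more than 2 SE above 0, which argues against a larger share of stem cells as the whole cause. An Esr1 UMI was found in 29.1% of clone stem cells, while the upper 95% limit in clone enterocytes and goblet cells was 4.29%, which argues against free RNA. A candidate explanation is that reads from the receptor part of the CreERT2 allele were counted as Esr1: at 5000 UMIs per cell, 14.3% of clone stem and dividing cells with an Lgr5 UMI had an Esr1 UMI (27 of 189), against 5.08% without (9 of 177; Fisher's exact two-sided p = 0.00439 over cells, which are not independent replicates, and p = 0.31, 0.412, 0.0327 and 0.299 in mice 5, 6, 7 and 8). Of control stem and dividing cells, 3.38% of those with an Lgr5 UMI (5 of 148) and 0.308% of those without (1 of 325) had one (Fisher's exact two-sided p = 0.0128 over cells). Control cells carry the same allele but were sorted as GFP-negative, and EGFP and CreERT2 both lie in that allele. The gate may thus have selected against cells that express it, so the control shares do not weigh against this explanation. A higher level of the mouse's own Esr1 stays open, since counts per gene do not tell the 2 transcripts apart. Own Esr1 that is higher in Lgr5-expressing cells would give the same association with Lgr5, so that test cannot decide between them.

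Of the alpha-defensins, 6 were called higher in control cells of the 72 h mice, most of all in mice 7 and 8, while Defa21, Defa22 and Defa30 of mice 5 and 6 lay within the range of the 48 h mice. The mean Paneth share was 1.3 times that of the 48 h mice, far below the change in Defa36 (1113 against 17.6 CPM), which argues against more Paneth cells as the whole cause. In pool 2 the 6 genes of the 48 h mice reached at most 0.164 of their level in the 72 h mice, which argues against the pools as the whole cause. Gene variants that differ between mice cannot be told apart from other causes: the ratio of Defa36 to Defa24 in Paneth cells of the same mouse was at least 3.93 times higher in control than in clone cells, but mice 5, 6, 7 and 8 had 1, 3, 2 and 11 clone Paneth cells, and the gate itself may move the ratio. Other differences between the mice, such as litter, age or housing, stay open and untested.

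The secretory share was lower in the 48 h clones by a difference of -29.8 percentage points. Over named cells alone it was -31.1, which argues against the weight of unnamed cells in the total as the cause. That test leaves the unnamed cells out, so it cannot tell whether some of them were secretory cells. At the higher Leiden resolution the secretory share of the 48 h clones was 14.1%, against 8.82%, and the difference was -25.2. With variable genes chosen without those called within a class, they were 14.4% and -23.8, and at the lower resolution 8.82% and -30.0. Secretory cells left unnamed thus stay open as part of the cause. Wrong hashtag assignment cannot be told apart from a difference between gates: the difference was -29.3 with the top hashtag at 70% or more, but -11.9 with the Gaussian mixture, an unbalanced test that kept 960 cells of pool 1 and 155 of pool 2, with 16, 1, 9 and 79 clone cells in mice 1, 2, 3 and 4, of which 32 lay in a goblet cluster with a median of 1569 UMIs. Loss of cells to the mitochondrial limit cannot be told apart either, since the difference at a limit of 50% was -19.3 with an SD of 14.2 between mice. A time course of differentiation, which the design names, and the sorting of EGFP-bright cells into the clone gate stay open and untested.

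Other splits of the samples were counted for every count of genes. For control cells of both times the real split called 9 genes and the highest of the other 34 called 1. A share of 1 in 35 (0.0286) is the smallest these splits allow, and it is 1 of many such shares. The count also hung on single mice and on the pool term, so chance is not excluded. For the unblocked clone comparisons the real splits called 0 and the others at most 0 at 48 h, 32 at 72 h, 2 between clones and 0 for the change between times; 35 of 35 splits call at least 0 in any case, so they say nothing about chance. At 72 h the 8 splits that part the 4 pairs called at most 0, so the 32 came from a split that did not part all pairs. Chance cannot be excluded for the blocked change between times, where 6 of 35 splits called as many as the real 10, the highest 35. For the blocked comparisons within times there are 8 splits, too few for a share under 0.05: the real one called 95 at 48 h (highest other 17) and 198 at 72 h (highest other 2).

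Within classes, nothing can be said of chance where the real count was 0. For clones against control at 72 h in stem, dividing and goblet cells the highest other counts were 46, 39 and 43, where splits that part as many pairs called at most 0, 2 and 1. In stem and dividing cells the highest came from mice 5 and 6 against 7 and 8. Clones of mice 5 and 6 were in pool 2 and those of mice 7 and 8 in pool 1, with control cells reversed. A difference between animals therefore cannot be told apart from a gate difference that varies with the pool. Between control sets the highest other counts were 10, 6 and 5 in dividing, secretory progenitor and goblet cells, also with a real count of 0. Chance cannot be excluded between control sets in enterocytes (6 of 35 splits; real 4; highest other 12). With the block the splits are too few for a share under 0.05, with 4 in stem (real 85, highest other 1), 8 in dividing (68 and 38) and 4 in goblet cells (9 and 21).

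Single samples lay far from the other 3 of their group in 12 of 56 groups of shares and library values (21.4%) and in 34 of 456 groups of genes (7.46%). In 6 of the 12 and 7 of the 34 the other 3 samples were all 0, so that a few cells or UMIs set the sample apart by construction and no rate by chance applies. In the 48 h clones these were the dividing (40.0%) and Paneth (6.67%) shares of mouse 2, the dividing secretory (2.41%), enteroendocrine (2.41%) and secretory progenitor (1.20%) shares of mouse 3, its 83 cells and its median top hashtag of 48.6%, and the goblet share of mouse 4 (25.0%). In the 72 h clones they were the enteroendocrine (1.53%) and enterocyte (10.7%) shares of mouse 8, and in control cells the unnamed share of mouse 1 (4.83%) and the secretory progenitor share of mouse 5 (10.7%).

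Genes with a sample far from the others are given as log2 of CPM plus 1. In the 48 h clones, mouse 1 had Esam 0, Hsp90b1 8.15, Rgs13 3.62 and Tnfrsf11a 3.62. Mouse 2 had Bax 6.69, Clps 5.70, Defa30 10.3, Gm7861 6.64 and Id1 6.17. Mouse 3 had Chga 6.14, Chgb 7.89, Hes6 5.93, Ilvbl 4.07 and Sp5 0, and mouse 4 had Dclk1 3.15 and Hid1 4.07. In the 72 h clones, mouse 6 had Hmgb2 9.21 and mouse 8 had Chga 6.29, Gcg 8.63, Hsp90b1 9.98 and Slc12a2 9.60. In control cells, mouse 1 had Ccn1 5.96, Reg3g 9.19 and Sct 8.24, mouse 3 had Hspa5 10.1 and Spdef 5.66, mouse 4 had Defa34 3.39, Dpep1 4.75 and Top2a 7.35, mouse 5 had Id1 7.70, mouse 7 had Top2a 8.46, and mouse 8 had Cftr 6.18, Hid1 5.33 and Sp5 2.82.

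The clone-control difference changed between 48 h and 72 h, by an interaction term, in 6 lists (median log2): secretory progenitor 1.33, Paneth -2.74, goblet 1.11, tuft 2.50, G2/M 0.85 and oxidative phosphorylation -0.074. None of the 6 held with an estimated correlation (adjusted p 0.905 to 0.975), and fry called 0. Without mouse 2 the Paneth median was -0.34. With the block it changed in Chgb (2.82), Defa21 (-3.69), Defa30 (-5.21), Defa22 (-4.36), Gm15293 (-6.64), Defa5 (-6.65), Defa36 (-6.76), Gm7861 (-5.65), Defa34 (-7.85) and AY761184 (-7.33). Without mouse 2 all 9 defensin calls were lost, and without mouse 3 or 8 that of Chgb.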

How the results depend on the processing

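The alternatives with a mitochondrial limit of 50%, a top hashtag of at least 70%, both together, named cells alone, goblet and progenitor cells alone, sums of at least 10 cells over all cells, and any combination with the block were chosen after the data were seen. The count of calls for each class within a single comparison stayed at 0, and the secretory share at 72 h, between clones and between control sets stayed on its side of the threshold, under every alternative run, though the sign between clones (15.0 percentage points) changed with the mixture (-3.64) and both added limits (-2.16), and between control sets (-3.56) in pool 2 alone (4.03); leaving out a mouse gave 9.62 to 20.4 and -8.16 to -1.05. Where a value below changed, the cause was not tested unless fewer samples or tests explain it.

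The secretory difference at 48 h (-29.8 percentage points) lost its call with the Gaussian mixture (-11.9), the 50% limit (-19.3), both added limits (-15.7), the block (-29.8, smallest possible p 0.125), without Paneth cells (-27.9) and with goblet and progenitor cells alone (-22.8); leaving out a mouse gave -34.0 to -26.7, where 3 against 3 cannot pass. No cluster was named secretory progenitor at resolution 0.6, with the mixture, without the variable genes called within a class, at the 50% limit or with both limits, and 29 cells were at resolution 1.5, against 191. The change of the secretory difference between times (18.6) ranged from 12.8 to 22.8 without a mouse and passed without mouse 4. Over all mice the difference (-20.6) lost its call with the mixture (-10.1). The 4 classes called over all mice became 0 with the mixture, 2 with at least 3000 UMIs, 7 at resolution 1.5, 2 over named cells, and 2 to 5 without a mouse (2 without mouse 1, 2, 4 or 7).

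Without a gene filter, edgeR called 427 genes at 48 h, 297 at 72 h, 132 between clones, 187 between control sets and 115 for the change. DESeq2 called 63, 8, 1, 19 and 2. With the block 95, 198 and 10 were called at 48 h, at 72 h and for the change, against 0 without. The 50% limit gave 5 at 48 h, 1 between clones, 5 between control sets and 3 for the change, and with the block 342 at 48 h. The 70% minimum gave 3 at 48 h, and with the block 228 at 48 h and 4 for the change. Both together gave 34 at 48 h, and with the block 670 at 48 h. The mixture gave 3 at 72 h, 1 between clones and 0 between control sets. The 10% limit gave 2 at 72 h and 2 for the change. At least 3000 UMIs gave 2 between control sets. Without the pool term 0 were called between control sets. Sums of at least 10 cells gave 0 between control sets and 1 for the change, and with the block 48 at 48 h and 36 for the change.

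Within classes some alternatives leave fewer tests, so each count is set against the reported calls in the same tests. Against 4 stood 335 without a gene filter, 68 with DESeq2, 0 without the pool term, 47 with the 50% limit and 2 with both limits. Against 0 stood 14 with the mixture, 2 with the 10% limit, 3 with at least 20 cells per sum and 76 at resolution 0.6. With the block, the 70% minimum gave 159 against 68, both limits gave 117 against 77 and the 50% limit gave 225 against 162, though 0 of these in stem cells, against 85. Leaving out a mouse gave 0 to 128: 1 without 1 or 3 and 0 without 4, each against 0, and 9 without 6, 2 without 7 and 128 without 8, each against 4. With the block it gave 25 to 192: 25 without 5 and 192 without 6 (each against 68), 70 without 7 (against 77) and 125 without 8 (against 153).

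Leaving out a mouse gave 7 to 222 genes at 48 h with the block (16 without mouse 1, 7 without 2, 222 without 3, 186 without 4, 180 without 6) and 37 to 402 at 72 h with the block (over 1.5 times as many without 2, 333 without 3, 43 without 5, 402 without 6, 65 without 7, 37 without 8). It gave 0 to 1 at 72 h without the block (1 without 2 or 8), 0 to 53 between control sets (0 without 1, 3 or 4, 2 without 2, 18 without 5, 1 without 7, 53 without 8), 0 to 4 for the change (1 without 1 or 6, 3 without 5, 2 without 7, 4 without 8) and 2 to 37 for the blocked change (2 without 2, 37 without 4, 18 without 5).

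The lists called (10, 13, 7, 6 and 6) became 0, 3, 0, 1 and 0 with an estimated correlation, 6, 0, 2, 0 and 0 with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, and 0, 0 and 0 at 48 h, at 72 h and for the change with block and estimated correlation. The 70% minimum left 3 between control sets, and leaving out a mouse gave 5 to 10 for the change (10 without 8).

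Some results changed direction. Oxidative phosphorylation had medians of -0.264 (50% limit, adjusted p = 0.00125) and -0.336 (both limits, adjusted p = 0.000786) at 48 h, where the test had pointed up. Its calls between clones and for the change were lost with these limits, at medians of the other sign (0.0792 and 0.109, adjusted p = 0.986 and 0.792, then 0.121 and 0.178, adjusted p = 0.728 and 0.367). Mature enterocyte genes had a median of 0.76 for the change with both limits (adjusted p = 0.00946). The tuft list between control sets (median 0.249, test pointing down, adjusted p = 0.845) was called up without mouse 2 (median 0.723, adjusted p = 0.0427) or 7 (0.517, adjusted p = 0.016) and down without mouse 3 (-0.266, adjusted p = 3.47e-06) or 8 (-0.984, adjusted p = 0.000401), and leaving out a mouse gave medians up to 0.748. With both limits and the block, Enpep (-1.73), Maf (-2.38) and Mttp (-1.59) were lower at 48 h. The cause was not tested.

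Of 8086 values of named genes 6688 stayed on their side of the threshold (316 of them uncalled and with the other sign), 93 lost and 1302 gained a call and 3 reversed; of 1491 list values 1277 (141 of them uncalled and with the other sign), 149, 56 and 9. Depth limits the 48 h clones most, at 747178 UMIs in 110 cells: 0 tuft cells allow a share of up to 2.73%, and 0 UMIs of Neurog3 allow up to 4.02 CPM, beside 6.18 ± 7.03 CPM in control cells (SD, n = 4), but without mouse 3 they allow up to 11.1% and 6.69 CPM, which exclude nothing.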

Other observations

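No test was run for this part. Of the immune and endothelial lists 1 gene each had counts enough to be tested. Ptprc, the CD45 antigen, stood at 3.55 ± 4.14 CPM in the 48 h clones and 2.56 ± 3.34 CPM in their control cells, and at 0.952 ± 1.12 and 2.43 ± 3.10 CPM at 72 h. Esam stood at 7.10 ± 5.23 and 2.86 ± 1.08 CPM at 48 h, and at 5.20 ± 1.85 and 3.43 ± 0.50 CPM at 72 h (SD, n = 4). A Ptprc UMI was found in 38.5% of the tuft cells of the clones (5 of 13) and 37.1% of those of control cells (13 of 35), and in 0.514% of all other cells (10 of 1945). Most cells with a Ptprc UMI were thus tuft cells.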
